A study of Homo sapiens with 6 samples.

How the data were processed

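Total RNA of U251 cells was extracted with TRIzol and made into libraries with the VAHTS Universal V6 kit, per the labels' protocols. Each of the 6 libraries, 3 of cells given SLCDS and 3 controls, has 1 file of FPKM values deposited by the authors, on a linear scale. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, while the labels name a human cell line and all 16832 listed symbols are written as human symbols, 16528 of them matching a human RefSeq symbol. Which genome the reads were aligned to is therefore open, and no coordinates are printed. None of the 13 mitochondrially encoded genes is listed, so that sign of RNA quality could not be read.

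Groups and replicate numbers came from the sample titles. Depth was read from the steps between low FPKM values: 2302 of 3060 low genes (75.2%) had values in ratios of small whole numbers within a tolerance of 0.004, which gave depths relative to SLCDS replicate 1 of 0.984 and 1.02 for SLCDS replicates 2 and 3 and of 0.968, 0.967 and 1.008 for control replicates 1 to 3. Absolute depth was estimated from 317 genes with a single annotated transcript, 132 of which (41.6%) agreed within a window of 5%. FPKM sums were 310281, 301736 and 305621 in SLCDS and 295203, 296125 and 348904 in control, and the 100 most abundant genes held 21.7% to 26.2% of the sum, most in control replicate 3. Replicates were compared for duplicated libraries: the median chi-square of abundant genes was 1.09 to 1.55 in pairs without control replicate 3 and 26.77 and 26.95 in pairs with it, where counting alone gives 0.45, so no libraries were merged.

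Values were analysed as log2(FPKM + 1), so fold changes are on that scale, which understates the change of low genes. Genes with an FPKM of at least 1 in 3 or more libraries were kept, 11506 in all. SLCDS was compared with control in a linear model with limma 3.58.1 in R 4.3.3, with a variance prior that follows the mean, 2-sided tests and Benjamini-Hochberg adjustment over all tested genes. Genes are said to have risen or fallen at an adjusted p under 0.05, and counts with a 2-fold threshold also require an absolute log2 fold change of at least 1. The 45 gene lists, with 918 entries, were written before the data were examined, and the 35 lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, adjusted over the 35. Of these lists 20 were higher and 4 lower, and none of the 24 calls held with the correlation estimated from the data.

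Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 largest increases and 12 largest decreases among genes past both thresholds with a mean FPKM of at least 5 in the higher group and no overlap of the groups. It adds up to 4 called members of each list described, or where fewer than 2 were called the 2 most abundant tested members, and 22 fixed markers. Exceptions are named where they occur. Some genes picked by this rule, and 1 list, are not reported here, though counts of genes and lists include them. Transcript length and GC content came from the longest protein-coding transcript in GENCODE release 29, for 98% of tested genes. As an added alternative, each library's trend with both was removed with natural splines of 4 degrees of freedom.

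Alternatives listed before the data were examined were other pseudocounts (0.1 and 0.5), no filter or a mean FPKM of at least 5, 4 other scalings, other variance priors, a replicate block, each library left out in turn, camera with an estimated correlation, and fry. The procedure was tested on simulated data of 11506 genes, where the changed genes were drawn from those with a mean FPKM above about 5. With all 6 libraries it recovered 52%, 88%, 96% and 98% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, and 6.7% of calls were false. Without control replicate 3 it recovered 94% of genes changed by 0.5, and 2% of calls were false. The simulated noise was independent between genes and had the same spread in every library. It held no outlying library and no correlated genes, so these shares need not hold for the real data or for low genes. Gene order along chromosomes came from RefSeq and was used only to group neighbouring genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.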

Results

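Gene expression was measured by RNA sequencing in U251, an established human glioma cell line. In 3 libraries the cells had been kept for 18 days with SLCDS, a combination of small molecules whose components the labels do not spell out, and in 3 control libraries the cells had received PBS without it. The labels give no culture time for the control, so time in culture may differ between the groups. The series title calls the treated cells neuronal-like, so the comparison asks how the transcriptome of SLCDS-treated U251 cells differs from that of untreated U251 cells. The deposited values are FPKM (fragment counts scaled by transcript length and by library depth) for 16832 gene symbols in each library. The steps between low FPKM values correspond to about 16800000, 16600000 and 17200000 fragments in SLCDS replicates 1 to 3. In control replicates 1 to 3 they correspond to about 16300000, 16300000 and 17000000 fragments. At these depths an FPKM of 1 on a transcript of 2000 nucleotides stands for 32.5 to 34.3 fragments.

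Prostaglandin D2 synthase, PTGDS, had the largest increase on the log2(FPKM + 1) scale among the genes named by rule. It went from 28.4 ± 5.34 FPKM (SD, n = 3) in control to 204 ± 8.0 FPKM in SLCDS (log2 fold change 2.81, SE 0.13, limma, adjusted p = 0.000228). The netrin receptor gene UNC5B rose from 1.06 ± 0.423 to 8.28 ± 0.168 FPKM, the calcium channel subunit gene CACNG7 from 0.830 ± 0.139 to 7.0 ± 0.369 FPKM, and the neural adhesion molecule gene L1CAM from 0.557 ± 0.144 to 5.4 ± 0.365 FPKM. By the ratio of mean FPKM, L1CAM (9.7), CACNG7 (8.43) and UNC5B (7.79) rose more than PTGDS (7.17). GDF15, a stress-induced secreted cytokine, rose from 16.6 ± 5.73 to 70.2 ± 3.91 FPKM. In the other direction the elastase gene CELA1 fell from 35.5 ± 6.86 to 2.63 ± 0.233 FPKM (log2 fold change -3.31, SE 0.14; limma, adjusted p = 0.000214). GFAP, the intermediate filament of astrocytes, fell from 339 ± 23.3 to 135 ± 7.31 FPKM (log2 fold change -1.32, SE 0.09; limma, adjusted p = 0.000596).

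Further genes with large increases were the proteoglycan gene BGN (log2 fold change 2.02), LCNL1 (2.01), which is the neighbour of PTGDS, the growth factor binding protein gene IGFBP3 (1.97), CAVIN2 (1.57), METTL7B (1.55) and PHLDB2 (1.52). On the log2(FPKM + 1) scale the largest decreases after CELA1 among the genes named by rule were those of the secreted NODAL antagonist gene LEFTY2 (log2 fold change -2.69), which went from 12.1 ± 2.27 to 1.01 ± 0.111 FPKM, the calcification inhibitor gene MGP (-1.73), the adhesion molecule gene VCAM1 (-1.66), ID2 (-1.60), ANKRD1 (-1.57) and RIPPLY1 (-1.54). SCRG1 (-1.49), SCUBE3 (-1.37) and the neuropeptide Y receptor gene NPY1R (-1.34) also fell. The FPKM ranges of the 2 groups did not overlap for any of these genes, which the rule that picked them required. BIN2, the neighbour of CELA1, was singled out after its values were seen, and fell from 1.81 ± 0.190 to 0.233 ± 0.0765 FPKM (log2 fold change -1.19; limma, adjusted p = 0.000688).

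Of 11506 genes tested with limma, 77 were higher and 25 lower in SLCDS by 2-fold or more at an adjusted p under 0.05. At any size of change 701 genes passed, 492 of them higher and 209 lower, and 85.4% of the 701 changed by less than 2-fold. FPKM ranges of the 2 groups did not overlap for 3353 genes, 29.1% of those tested. The average share over the 10 splits of the libraries into 3 and 3 is 10%. Genes vary together, so a single split can lie far from 10% without any effect of SLCDS. The share was not counted for the other splits, so 29.1% cannot be called an excess. Control replicate 3 stood apart from all other libraries. Its Pearson correlation across genes with the other controls was 0.9765 and 0.9767, against 0.9969 between control replicates 1 and 2 and 0.9966 to 0.997 among the SLCDS libraries; these are correlations over genes, which are not independent replicates. Without control replicate 3, 3191 genes passed, 1838 higher and 1353 lower, and these included all 701. With the transcript length and GC trend of each library removed, a setting chosen after the data were seen, 2039 genes passed, 1054 higher and 985 lower.

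**Figure D1:**
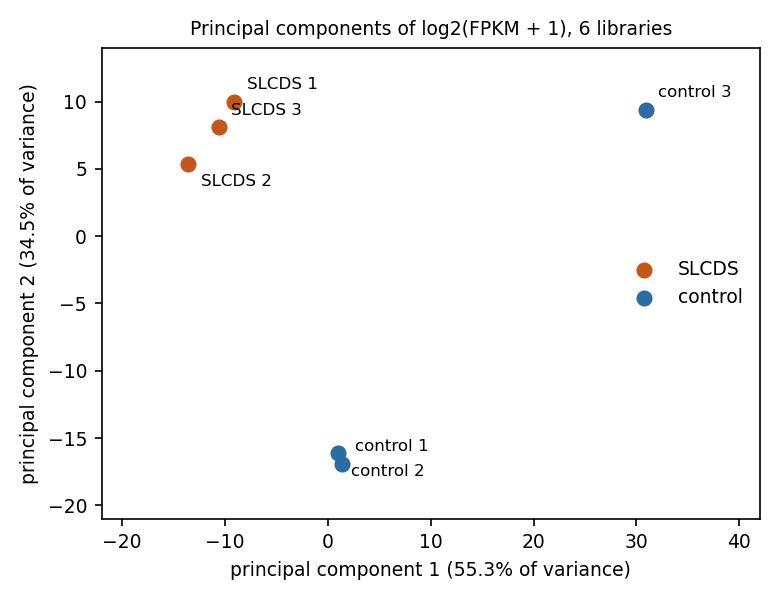
Principal components of log2(FPKM + 1) of the 11506 tested genes, with 1 point per library and the share of variance on each axis. Component 1 (55.3% of variance) sets control replicate 3, at 30.9, apart from the other 5 libraries, and component 2 (34.5%) sets the SLCDS libraries, at 5.4 to 10, apart from control replicates 1 and 2, at -16.9 and -16.1, but not from control replicate 3, at 9.4.

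**Figure D2:**
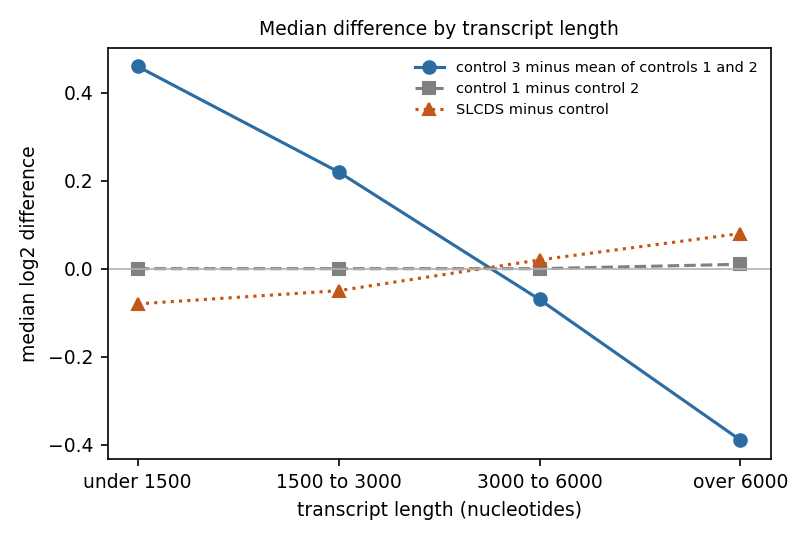
Median log2 difference (vertical axis) of genes in 4 classes of transcript length in nucleotides (horizontal axis), for control replicate 3 against the mean of control replicates 1 and 2 (circles), control replicate 1 against 2 (squares) and SLCDS against control (triangles). The circles go from 0.46 under 1500 nucleotides to -0.39 over 6000, and the triangles from -0.08 to 0.08. The triangles include control replicate 3. Across genes, Spearman's rho of the SLCDS difference with transcript length was 0.31 against all controls and -0.18 against control replicates 1 and 2 only.

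Neuronal genes moved in both directions, and the classical markers of neurons did not pass the test. TUBB3, the neuronal beta-tubulin, stood at 29.5 ± 1.08 FPKM in SLCDS and 39.4 ± 5.12 FPKM in control (n = 3 each; limma, adjusted p = 0.0671), and MAP2 at 14.7 ± 0.485 and 18.5 ± 4.63 FPKM (limma, adjusted p = 0.458). Without control replicate 3 both were lower in SLCDS, with limma adjusted p values of 0.00109 for TUBB3 and 5.99e-05 for MAP2; over 18 other settings these ranged from 0.00109 to 0.271 and from 5.99e-05 to 0.735. The neurofilament gene NEFL stood at 28.9 ± 0.480 and 26.0 ± 3.05 FPKM and the synaptic vesicle gene SYP at 1.08 ± 0.109 and 0.714 ± 0.272 FPKM. Both were higher in SLCDS without control replicate 3, with limma adjusted p values of 0.0106 for NEFL and 0.0134 for SYP, and over the other settings these ranged from 0.0106 to 0.723 and from 0.0134 to 0.607. DCX (0.319 and 0.330 FPKM), RBFOX3 (0.0110 and 0.00687 FPKM), SYN1 (0.887 and 0.530 FPKM) and the proneural factor gene NEUROG2 (0.622 and 0.902 FPKM) lay under the expression filter in SLCDS and control.

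**Figure D3:**
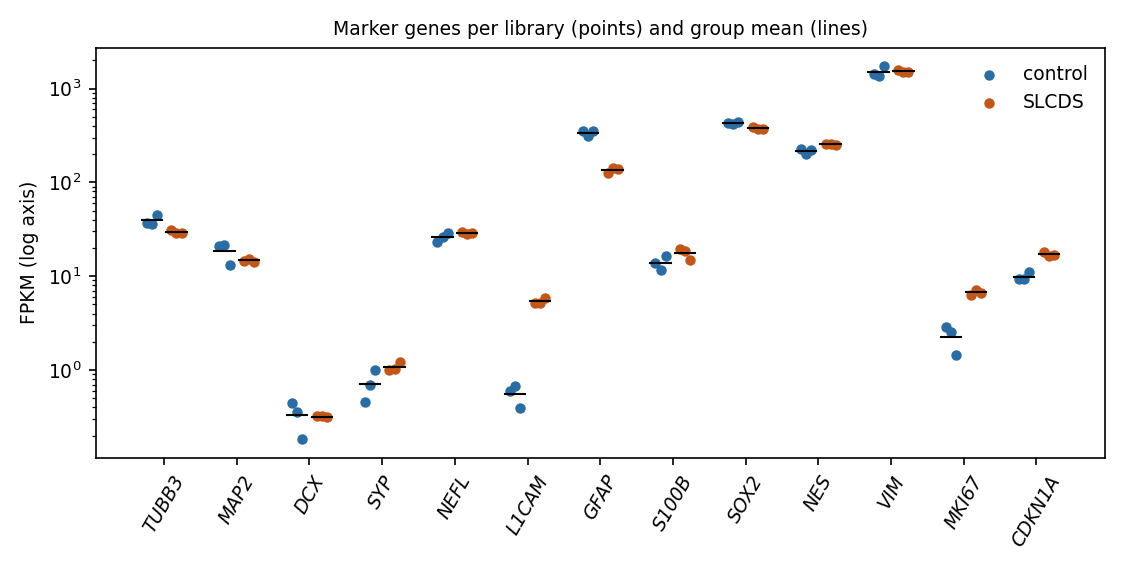
FPKM on a log axis of marker genes in each library (points, 3 per group) with the mean of each group (lines). L1CAM, MKI67 and CDKN1A lie higher in SLCDS and GFAP lower, while NEFL and VIM overlap between the groups.

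In the pan-neuronal list 4 of 14 tested members rose, none fell and 10 did not pass. Adjusted over the list alone 5 passed, 4 higher and 1 lower. Over all genes 9 were higher and 3 lower without control replicate 3. The risers over all libraries were L1CAM, the growth cone gene GAP43 (log2 fold change 0.62), CRMP1 (0.58) and DPYSL5 (0.49). The list was higher in SLCDS by camera (adjusted p = 0.0204), and the adjusted p was 0.176 with an estimated correlation, 0.127 without control replicate 3 and 0.0659 with the length and GC trend removed. Over 18 other settings at the preset correlation it ranged from 0.0081 to 0.89, the last with a mean FPKM of at least 5. Among synaptic genes 2 of 15 rose, NRXN3 (log2 fold change 1.00) and the vesicle calcium sensor gene SYT1 (0.54), none fell, and 4 passed adjusted over the list alone. SYT1 passed in only 9 of 18 other settings. The synaptic list was higher by camera (adjusted p = 0.00877), with an adjusted p = 0.176 with an estimated correlation, and 0.00135 to 0.0966 over the other settings. Voltage-gated channel genes were higher as a list, with 3 of 8 rising, among them SCN9A (log2 fold change 1.07), none falling, and 6 passing adjusted over the list alone. By camera the channel list was higher (adjusted p = 7.57e-07), with an adjusted p = 0.113 with an estimated correlation.

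Of the glutamatergic list 2 of 5 tested members rose, the vesicular transporter gene SLC17A7 (0.493 ± 0.0862 to 1.98 ± 0.278 FPKM) and the receptor gene GRIA2 (log2 fold change 0.57), none fell, and 3 passed adjusted over the list alone. Its camera test gave an adjusted p of 0.0201, and an adjusted p of 0.353 with an estimated correlation, 0.27 without control replicate 3 and 0.0546 with the length and GC trend removed, over a range of 0.00439 to 0.27. GRIA2 passed in only 9 of 17 other settings. In the GABAergic list 4 of 5 tested members fell and none rose, and all 5 were lower adjusted over the list alone. The GABAergic list was lower by camera (adjusted p = 5.10e-06), with an adjusted p = 0.113 with an estimated correlation. The 4 were DLX1 (log2 fold change -0.64), DLX5 (-0.63), DLX2 (-0.45) and DLX6 (-0.43), homeobox factors of the forebrain. The other member, the GABA synthesis enzyme gene GAD1 (log2 fold change -0.37), named after its values were seen, missed the threshold over all genes (limma, adjusted p = 0.0834). The axon guidance list had 2 of 26 members rising, UNC5B and EPHB2 (log2 fold change 0.52), none falling, 2 passing adjusted over the list alone, and no call by camera (adjusted p = 0.0971). Over the other settings this ranged from 0.0143 without control replicate 1 to 0.568 with the trend removed, and without control replicate 3 the list leaned lower, with a median of -0.05. With the trend removed the limma adjusted p of EPHB2 was 0.0826, and it ranged from 0.00092 to 0.0902 over the other settings.

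Astrocyte genes were lower as a list: of 16 tested members 4 fell, 1 rose and 11 did not pass, and adjusted over the list alone 8 were lower and 1 higher. Camera placed the astrocyte list lower (adjusted p = 0.00133), with an adjusted p = 0.291 with an estimated correlation, and 0.000279 to 0.067 over the other settings. Besides GFAP, the gap junction gene GJA1 fell from 118 ± 13.0 to 58.8 ± 1.10 FPKM, and MLC1 (log2 fold change -0.40) fell less. SPARCL1 (-0.36), named outside the rule, also fell. The glutamine synthetase gene GLUL rose (log2 fold change 0.54). S100B stood at 17.8 ± 2.45 FPKM in SLCDS and 14 ± 2.4 FPKM in control (limma, adjusted p = 0.286). The neural progenitor list had 1 of 15 members rising, OLIG2 (log2 fold change 0.59), and 1 falling, ZIC1 (-0.40). Each of these calls held in only 9 of 17 other settings. Adjusted over the list alone 2 members were higher and 4 lower. Camera made no call (adjusted p = 0.499), the median of the list lying below 0 and its mean above. The stem cell factor SOX2 stood at 376 ± 10.2 and 431 ± 12.7 FPKM, NES at 254 ± 3.31 and 216 ± 13.3 FPKM and VIM at 1524 ± 39.7 and 1507 ± 191 FPKM in SLCDS and control, and none of these passed over all libraries. Without control replicate 3 SOX2 was lower (limma, adjusted p = 0.00919), and NES (0.00539) and S100B (0.0105) were higher. Each of SOX2, NES and S100B passed in 2 of 18 other settings, and VIM in none.

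The glioma stem list was higher by camera (adjusted p = 0.0103), with L1CAM and OLIG2 rising among 12 tested members, none falling; adjusted over the list alone 7 were higher and 1 lower. Its adjusted p was 0.176 with an estimated correlation and 0.119 without control replicate 3, with a range of 0.00755 to 0.402 over the other settings. Among markers of other cell types, the oligodendrocyte list had 1 of 7 members rising, OLIG2, and 1 falling (2 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.751, with a median above 0 and a mean below). In the Schwann cell and neural crest list EGR2 rose (log2 fold change 0.93) and 1 gene fell among 6 tested (2 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.237). In the fibroblast and pericyte list 2 of 7 rose, the smooth muscle actin gene ACTA2 (log2 fold change 1.27), whose sequence is close to that of other actins, and PDGFRB (1.03), and adjusted over the list alone 2 were higher and 1 lower (camera, adjusted p = 0.213).

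Proliferation genes were higher in SLCDS. MKI67, the Ki-67 antigen gene, rose from 2.27 ± 0.748 to 6.71 ± 0.412 FPKM (log2 fold change 1.26, SE 0.17; limma, adjusted p = 0.00593), and the mitotic genes UBE2C (1.19), AURKB (1.07) and BIRC5 (1.06) rose with it. In the G2/M list 23 of 29 tested members rose, none fell, and 26 passed adjusted over the list alone, with a median log2 fold change of 0.62. The G2/M list was higher by camera (adjusted p = 3.48e-22), with an adjusted p = 0.0513 with an estimated correlation. In the S phase list 14 of 28 rose, none fell, and 15 passed adjusted over the list alone. By camera the S phase list was higher (adjusted p = 1.78e-10), with an adjusted p = 0.113 with an estimated correlation. The nucleotide synthesis genes RRM2 (log2 fold change 1.19), TYMS (1.06) and TK1 (1.00) and the replication licensing gene CDC6 (0.99) led it. Replication-dependent histone genes are near-identical copies whose fragments may be split between members. Of these 6 of 11 rose, none fell, and 10 passed adjusted over the list alone. By camera the histone list was higher (adjusted p = 2.61e-07), with an adjusted p = 0.113 with an estimated correlation. The risers included H4C8 (log2 fold change 0.70), H2BC11 (0.53), H2BC4 (0.50) and H2AC6 (0.45). H4C8 passed in only 9 of 18 other settings.

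Some genes of growth arrest rose beside those of the cell cycle. CDKN1A, which encodes the p21 inhibitor, rose from 9.92 ± 1.08 to 17.2 ± 0.734 FPKM (limma, adjusted p = 0.00393), GAS1 from 106 ± 5.71 to 239 ± 13.1 FPKM and GADD45A from 14.9 ± 1.90 to 28.2 ± 1.97 FPKM. These were 3 of 13 tested members of the CDK inhibitor and growth arrest list, none fell, and adjusted over the list alone 4 were higher and 1 lower. The growth arrest list was higher by camera (adjusted p = 0.0305), with an adjusted p = 0.314 with an estimated correlation, and 0.0153 to 0.0958 over the other settings, highest without control replicate 3.

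**Figure D4:**
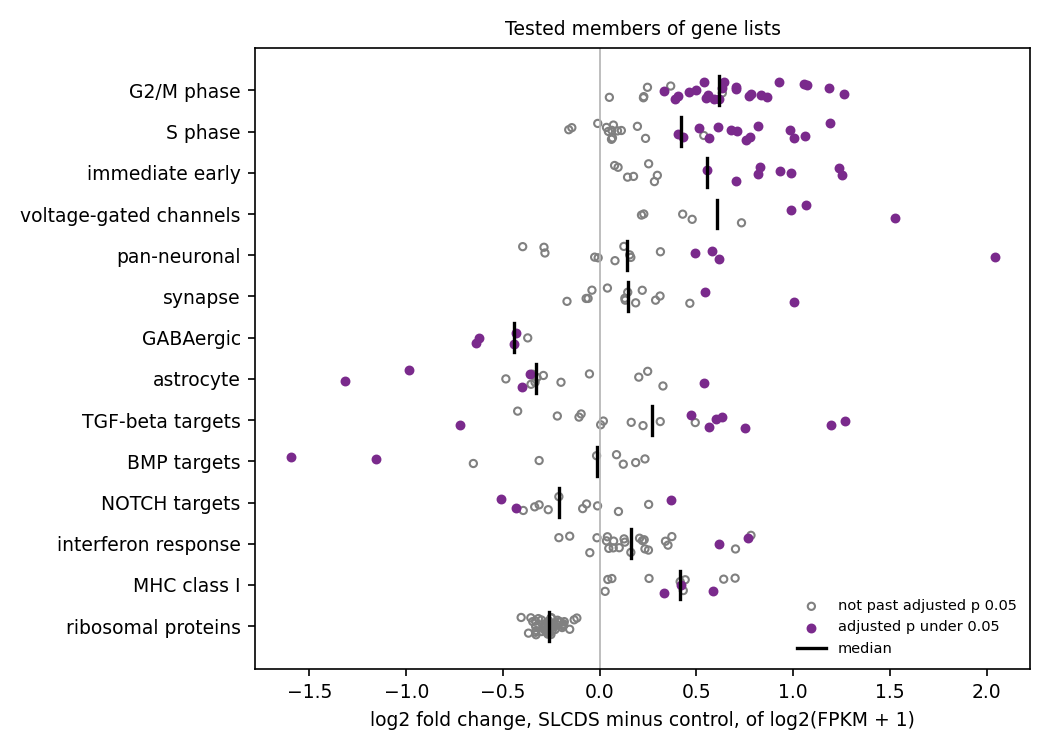
Log2 fold change of each tested member of 14 gene lists (points; filled where the adjusted p is under 0.05) with the list median (black lines). The G2/M list has its median at 0.62 and the astrocyte list at -0.33, and no ribosomal protein gene passed on its own.

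Feedback genes of the ERK cascade and some immediate early genes were higher. DUSP6, an ERK phosphatase gene, rose from 11.5 ± 0.158 to 28.4 ± 1.17 FPKM (limma, adjusted p = 0.000261), and the transcription factor genes ETV4 (log2 fold change 1.25), ETV5 (0.99) and EGR2 rose too. In the immediate early list 8 of 15 tested members rose, none fell, and 9 passed adjusted over the list alone. FOS (log2 fold change 0.08), FOSL1 (0.28), JUN (0.18), JUNB (0.25), JUND (0.14) and IER2 (0.095), named outside the rule, did not pass over all libraries. Without control replicate 3, 14 of the 15 members were higher. Camera placed the immediate early list higher (adjusted p = 1.78e-10), with an adjusted p = 0.191 with an estimated correlation. In the cAMP and CREB target list ATF3 rose (log2 fold change 0.56), 1 of 10, none fell, and 4 passed adjusted over the list alone. The CREB target list was higher by camera (adjusted p = 0.0168), with an adjusted p = 0.176 with an estimated correlation, and 0.0078 to 0.17 over the other settings. DUSP1 stood at 13.4 ± 0.377 and 10.8 ± 1.65 FPKM and CREB5 at 7.77 ± 0.491 and 4.74 ± 1.44 FPKM in SLCDS and control, short of the threshold. Without control replicate 3 both were higher, with limma adjusted p values of 0.000323 for DUSP1 and 0.00227 for CREB5. Each passed in 2 of 18 other settings.

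Among targets of BMP signalling, ID2 fell from 11.9 ± 1.58 to 3.30 ± 0.798 FPKM and ID3 from 32.5 ± 7.76 to 13.8 ± 0.758 FPKM, 2 of 9 tested members, none rose, and 4 were lower adjusted over the list alone, while camera made no call (adjusted p = 0.0969, with a range of 0.0177 to 0.499 over the other settings, 4 of 18 under 0.05). ID1 stood at 1.38 ± 0.458 and 2.80 ± 1.09 FPKM in SLCDS and control (limma, adjusted p = 0.164). TGF-beta targets were higher as a list, 7 of 18 rising and 1 falling, with 8 higher and 2 lower adjusted over the list alone. By camera the TGF-beta target list was higher (adjusted p = 0.00228), with an adjusted p = 0.113 with an estimated correlation, and 0.000689 to 0.0519 over the other settings. ACTA2, the matricellular gene CCN2 (log2 fold change 1.20) and TGFBI (0.75) rose, and PMEPA1 fell (-0.72).

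NOTCH targets were lower by camera (adjusted p = 0.0343), with an adjusted p = 0.205 with an estimated correlation. Of 13 tested members NRARP (log2 fold change -0.51) and DTX4 (-0.44) fell and CCND1 rose (0.37). Adjusted over the list alone 1 was higher and 4 lower. DTX4 passed in only 8 of 17 other settings and CCND1 in 9 of 18. The median of the list was -0.21 over all libraries and -0.03 without control replicate 3, where the camera adjusted p was 0.068, within a range of 0.0153 to 0.175 over the other settings. HES1 stood at 9.43 ± 0.326 and 12.9 ± 2.91 FPKM (limma, adjusted p = 0.189). In the WNT target list 3 of 11 rose, TNFRSF19 (log2 fold change 0.78), LGR5 (0.62) and CCND1, none fell, 4 were higher and 2 lower adjusted over the list alone, and camera made no call (adjusted p = 0.0969); AXIN2 stood at 2.82 ± 0.225 and 2.31 ± 0.365 FPKM. LGR5 passed in only 9 of 17 other settings. The hedgehog readout GLI1 lay under the filter at 0.0730 FPKM in SLCDS and 0.0351 FPKM in control.

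Some matrix and mesenchymal genes were higher. MMP2, a gelatinase gene, rose from 15.5 ± 2.09 to 35.5 ± 1.68 FPKM, and TGFBI and LOXL2 (log2 fold change 0.37) rose with it, 3 of 18 tested members of the mesenchymal list, with none falling and 5 passing adjusted over the list alone. Camera placed the mesenchymal list higher (adjusted p = 0.00133), with an adjusted p = 0.113 with an estimated correlation. In the collagen and basement membrane list 4 of 19 rose, BGN, COL4A1 (log2 fold change 0.63), COL11A1 (0.58) and COL4A2 (0.57). The 1 member that fell was COL6A1 (-0.37), named outside the rule. In this list 5 were higher and 1 lower adjusted over the list alone. Camera gave it an adjusted p of 0.00417, and an adjusted p of 0.353 with an estimated correlation, and from 0.00117 to 0.175 over the other settings, highest without control replicate 3.

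Inflammatory secretory genes split, 5 of 14 rising and 2 falling, with 6 higher and 2 lower adjusted over the list alone. The inflammatory list was higher by camera (adjusted p = 0.00417), with an adjusted p = 0.314 with an estimated correlation, and 0.00109 to 0.102 over the other settings. IGFBP3, the urokinase gene PLAU (log2 fold change 1.33) and the adhesion molecule gene ICAM1 (1.22) rose, whereas the cytokine gene IL6 fell from 18.0 ± 1.43 to 9.04 ± 0.660 FPKM. Of the interferon response list 2 of 25 rose, RSAD2 (log2 fold change 0.77) and OAS2 (0.62), none fell, and 4 passed adjusted over the list alone. The interferon list was higher by camera (adjusted p = 0.00146), with an adjusted p = 0.424 with an estimated correlation. Without control replicate 3, 14 of the 25 were higher. The MHC class I list had 3 of 12 rising, the peptide transporter genes TAP1 (log2 fold change 0.59) and TAP2 (0.33) and the regulator gene NLRC5 (0.42), none falling, and 5 passing adjusted over the list alone. By camera the MHC class I list was higher (adjusted p = 0.000348), with an adjusted p = 0.383 with an estimated correlation. Without control replicate 3 all 12 were higher. Over 18 other settings the limma adjusted p of TAP1, 0.0498 over all libraries, ranged from 8.69e-06 to 0.208, that of TAP2 from 0.000864 to 0.211 and that of NLRC5 from 0.000943 to 0.122.

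More members of most lists passed over all genes when control replicate 3 was left out. In that fit 9 synaptic members were higher and 2 lower, 6 of 8 channel members were higher and none lower, and 4 axon guidance members were higher and 4 lower. The astrocyte list had 3 higher and 11 lower, the neural progenitor list 5 and 6, the glioma stem list 7 and 3, and the growth arrest list 4 and 2. The collagen and basement membrane list had 7 higher and 5 lower, its median going from 0.20 to 0.07, the mesenchymal list 10 and 2, the inflammatory list 10 and 2, and the TGF-beta target list 9 and 3. Among the remaining signalling lists the CREB targets had 5 higher and 1 lower, the NOTCH targets 1 and 5, the BMP targets 2 and 3, and the immediate early list 14 and none. With the length and GC trend removed the synaptic list had 5 higher and 1 lower, the astrocyte list 2 and 10, and the collagen list 6 and 3.

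Cytosolic ribosomal protein genes were lower as a list by camera (adjusted p = 1.66e-08; adjusted p = 0.435 with an estimated correlation), but none of the 48 tested members passed on its own, over all genes or adjusted over the list alone. Their median log2 fold change was -0.26 over all libraries and -0.09 without control replicate 3, where 17 were lower. RPS18, among the most abundant, stood at 565 ± 8.96 FPKM in SLCDS and 691 ± 154 FPKM in control. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p values measure only the spread between these libraries, which may be technical.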

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

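The removal of the length and GC trend was chosen after the data were seen; the other settings were planned. No gene picked by rule changed direction where it passed in the main fit or in the setting. Among those that passed in neither some did, such as ENO1, with a log2 fold change of -0.097 over all libraries and 0.038 without control replicate 3. Of 138 genes picked by rule and tested, 38 to 40 lost their call without 1 SLCDS library, 27 without control replicate 1 or 2 and 22 with the replicate block; 19 gained one without control replicate 3 and 18 with the trend removed. The 77 higher genes became 170 with a pseudocount of 0.1, 117 with 0.5, 36 with a mean FPKM of at least 5 and 185 when libraries were rescaled to a common sum. The 25 lower genes became 43 with a pseudocount of 0.1 and 40 after that rescaling. That rescaling also changed the weight of the pseudocount, the scaling between libraries and the filter, which passed 12660 genes, so its effect has no single source. The 701 genes at any size became 324 with a mean FPKM of at least 5, where 8394 genes were tested, and 2039 with the trend removed. Leaving out 1 library gave 66 to 95 higher, 21 to 30 lower and 276 to 3191 genes at any size. At any size the count was 276, 281 and 287 without SLCDS replicates 1, 2 and 3, 412 and 417 without control replicates 1 and 2, which leaves fewer samples, and 3191 without control replicate 3. Gene lists were 17 to 21 higher and 3 to 6 lower over the same fits. The 4 lower lists became 2 with no filter. With a mean FPKM of at least 5 the lists were 12 higher and 2 lower, since fewer members were tested. Camera with an estimated correlation called 0 higher and 0 lower at an adjusted p under 0.05, the lowest being 0.0513. Fry called 19 higher and 4 lower, but not all the same lists as camera in the main fit. By fry the interferon (adjusted p = 0.137), MHC class I (0.0921), unfolded protein (0.0987) and ribosomal protein (0.244) lists were not called. Fry instead called the fibroblast and pericyte (adjusted p = 0.00138) and WNT target (0.0283) lists higher and the neural progenitor list (0.0321) lower. The first principal component held 52.2% to 58.8% of the variance. As a replicate block the label numbers left 78 higher, 25 lower and 455 at any size, and no list lost its call. The labels do not say whether the numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.326, 0.36 and 0.065, and SLCDS replicate 1 correlated best with control replicate 3. SLCDS replicate 2 gave 0.365 with control replicate 1, 0.36 with control replicate 2 and -0.406 with control replicate 3. Control replicate 3 dominates the control deviations, so the check cannot tell whether the numbers pair the libraries. Genes under the filter, at these depths below 32.5 to 34.3 fragments on 2000 nucleotides, were not tested.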

Other observations

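The tests of transcript length and depth in control replicate 3, of the cell cycle list without control replicate 3, of chromosome 2 copy number, of chromosome 2 without control replicate 3 and of ERK targets were chosen only after the results they concern were seen.

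Some stress genes were higher. In the unfolded protein and integrated stress response list 3 of 20 tested members rose, the pseudokinase gene TRIB3 (log2 fold change 0.96), the phosphatase subunit gene PPP1R15A (0.61) and ATF3 (0.56), none fell, and 4 passed adjusted over the list alone, while 14 rose without control replicate 3 and 9 with the trend removed (camera, adjusted p = 0.00129; adjusted p = 0.410 with an estimated correlation). Of the hypoxia list 4 of 15 rose, the peptide hormone gene ADM (1.05), NDRG1 (0.89), the carbonic anhydrase gene CA12 (0.80) and the glucose transporter gene SLC2A1 (0.43), none fell, and 5 passed adjusted over the list alone, while 8 rose and 1 fell without control replicate 3. Its camera adjusted p was 0.0343, with 0.420 as the adjusted p with an estimated correlation, 0.156 without control replicate 1, 0.0571 without SLCDS replicate 3 and 0.059 with the trend removed, within a range of 0.0108 to 0.175. In the lysosome list GPNMB (1.00) and WIPI1 (0.44) rose among 21 tested, both passing adjusted over the list alone, with no call by camera over all libraries (adjusted p = 0.237; 0.00426 to 0.729 over the other settings). The lowest was without control replicate 3, where 8 were higher and 1 lower. No member of the glycolysis list (18 tested; camera, adjusted p = 0.755) or of the nuclear oxidative phosphorylation list (29 tested; camera, adjusted p = 0.0768) passed limma's test, over all genes or adjusted over the list alone. These results depend on control replicate 3. Without it the glycolysis list was higher by camera (adjusted p = 0.0406, with 7 members higher and 1 lower), and the median of the oxidative phosphorylation list went from -0.10 to 0.05, with 4 members higher. Over the other settings the camera adjusted p ranged from 0.0406 to 0.995 for glycolysis and from 0.00662 to 0.367 for oxidative phosphorylation, which was lower at an adjusted p under 0.05 in 6 of 18 settings, most clearly without control replicate 2. GAPDH stood at 1305 ± 26.8 FPKM in SLCDS and 1311 ± 257 in control, ENO1 at 653 and 705, ATP5F1B at 237 and 236 and COX7C at 186 and 201. Of 23 cholesterol synthesis genes MSMO1 fell (-0.32), and 2 were higher and 1 lower adjusted over the list alone, or 3 and 5 over all genes without control replicate 3 (camera, adjusted p = 0.237).

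Several lists had too few tested members for camera. Among neurotrophins and their receptors BDNF (log2 fold change 0.53) and GFRA1 (0.74) rose and NTRK2, the BDNF receptor gene, fell from 1.79 ± 0.497 to 0.317 ± 0.0429 FPKM, 3 of 4 tested, and adjusted over the list alone 2 were higher and 1 lower. Both tested endothelial markers rose, CDH5 (1.02) and ENG (0.78), and both passed adjusted over the list alone, while 10 more lay under the filter. The single tested pluripotency gene, DNMT3B, rose (0.47), also adjusted over the list alone. Of 4 hedgehog targets SPP1 rose (0.71), SFRP1 stood at 17.1 and 16.1 FPKM in SLCDS and control, and 1 was higher and 1 lower adjusted over the list alone; the list had enough members in 2 other settings and was higher by camera in both (adjusted p = 0.0276 with no filter and 0.0452 rescaled to a common sum). None of 4 neuronal transcription factors passed, with 1 lower adjusted over the list alone; POU3F2 stood at 85.7 and 96.3 FPKM and SOX4 at 60.7 and 70.3 FPKM. Without control replicate 3, and with the trend removed, 3 of the 4 were lower. No called gene was found over all genes among 3 cholinergic and monoaminergic genes (ACHE 17.8 and 15.9 FPKM), 2 myeloid genes (CD68 4.05 and 2.79 FPKM), 4 epithelial genes (KRT18 3.28 and 3.52 FPKM) or 4 metallothioneins (MT2A 457 and 382 FPKM). Adjusted over the list alone 1 of the myeloid genes was higher, and 0 of the others.

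With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large cannot fall under 0.1. The real split gave 102 genes at 2-fold, 701 at any size and 24 lists, each being 1 of the 10 splits to reach its value, and the highest of the other splits gave 0, 0 and 15.

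Control replicate 3 stood apart from control replicates 1 and 2. Its log2 difference from their mean fell with transcript length (Spearman's rho across genes -0.73) and rose with GC content (0.55), against 0.03 and 0.06 between control replicates 1 and 2, and removing both trends took away 62.8% of its variance over genes. A lower depth is argued against by its relative depth of 1.008, above those of the other controls. After the correction its interferon response list still lay higher, with a median difference of 0.19 where random lists gave -0.08 to 0.09, and 19 of 25 members above 0. The random lists treat genes as independent, while this list had an estimated correlation of 0.435. Their range may therefore be too narrow, and the difference rests on 1 library. A difference in fragment length or RNA quality may account for most of the gap and a higher interferon response for part of the rest, both as hypotheses.

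The higher cell cycle genes kept their size under both technical explanations tested. With the length and GC trend removed the G2/M list kept 92.4% of its median log2 fold change, and without control replicate 3 it kept 90%. Neither accounts for the difference, so a larger share of cycling cells in the SLCDS cultures is a hypothesis that stays open, beside differences in culture density, on which the labels give nothing, and in time in culture, which they do not give for the control.

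Genes of chromosome 2 lay slightly lower in SLCDS, as did those of some other chromosomes. Uncorrected, the median log2 fold change was -0.037 on chromosome 2, -0.052 on chromosome 16 and -0.04 on chromosome 22. With the trend removed the chromosome 2 median was -0.061 over 760 genes, where random lists gave -0.035 to -0.010. A second form of the test, without control replicate 3, was run because chromosome 16 had the same median. It gave -0.068 for chromosome 2. Chromosome 17 had medians of -0.049 and -0.046 in the 2 forms. Length and GC as fitted do not account for the lower chromosome 2 median. A lower copy number may be a cause: 14 of 15 blocks of neighbouring genes (93.3%) lay below the other chromosomes, and 13 (86.7%) in the second form. The block count takes only the direction of each block. It cannot say whether a shift as small as -0.061 is one that a lower copy number would give. Copy number stays open, since the share was 100% on chromosome 22 and 80% on chromosomes 7 and 16 in the first form and 80% on chromosome 22 in the second. Of 23 chromosomes 7 and 6 passed a Benjamini-Hochberg adjusted p of 0.05 in the 2 forms, in 2-sided tests and in both directions. Chromosomes 2, 16 and 17 lay below random lists in the first form, and chromosomes 2, 7, 16 and 17 in the second. Chromosomes 3, 5, 6 and 15 lay above random lists in the first form, and chromosomes 1 and 15 in the second. The p values came from 10000 random lists, which treat neighbouring genes as independent.

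Higher ERK signalling may stand behind the genes that rose in the immediate early list. Of 5 further genes of a published MAPK activity list, 3 rose, DUSP4 (log2 fold change 1.13), EPHA2 (0.94) and CCND1 (0.37), while PHLDA1 (269 and 282 FPKM) and EPHA4 (11.5 and 10.7 FPKM) did not pass limma's test. The count rests on CCND1, which passed in 9 of 18 other settings (limma, adjusted p from 0.00154 to 0.192), and without it 2 would have risen, too few to decide. The median log2 fold change of the immediate early list was 0.56 over all libraries, 0.57 with the length and GC trend removed and 0.61 without control replicate 3, which argues against either as its whole cause. Higher ERK signalling stays open as a hypothesis.

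Among the 102 genes changed by 2-fold, 4 pairs were direct neighbours: BIN2 and CELA1, P3H2 and CLDN1, FIBCD1 and LAMC3, and PTGDS and LCNL1. Random lists of 102 genes, not matched on expression, had a median of 1 pair (1-sided permutation p = 0.0133 over 10000 lists). The pairs were noticed before the test, and whether fragments were shared between neighbours was not tested.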
